A study of Mus musculus with 6 samples.

How the data were processed

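In situ Hi-C was done on C57BL/6 mouse embryonic fibroblasts at population doubling 2, 8 and 14 (PD2, PD8 and PD14), with 6 libraries, 2 per group. The deposited values are balanced contact signal per pair of 40 kb bins, in 3 matrices, 1 per group. Per the submitters' processing notes, reads were converted with bcl2fastq and processed with HiC-Pro 2.7.8 on mm10. Per the series design text, the libraries of a group were processed together. Each matrix therefore holds pooled libraries, and neither a test between groups nor a replicate SD was possible. All 3 matrices sum to the same signal, so their totals carry no depth. Groups were taken from the sample labels, and all 3 pairs of groups were compared.

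Depth was recovered from the values. A balanced value is a whole number of contacts times a factor for each of its 2 bins, and these factors were solved for so that small values became whole. Bins were kept when at least 90% of their small values were whole within 0.05. This gave 63486, 63394 and 63401 usable bins on autosomes and chromosome X at PD2, PD8 and PD14 (95.7% to 96.0% of usable bins), in which 99.9998%, 99.9995% and 99.9998% of small values were whole. The recovered contacts between different bins numbered 87844228, 107279081 and 104477458. For noise, the contacts of a matrix were split at random into 2 parts and each part was balanced again. For depth, contacts of PD8 and PD14 were thinned at random to the number at PD2, keeping 81.9% and 84.1%. Intervals are 95% Wilson intervals for shares and exact Poisson (conditional binomial) intervals for local contacts, and cover counting error only.

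Values were computed on the 19 autosomes unless stated, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Contact shares used balanced signal with same-bin pairs left out. Compartment scores came from 200 kb bins with at least 60% usable 40 kb bins. Per autosome, contacts over the distance expectation (clipped at percentile 99.9) were correlated between bins, and the first eigenvector was taken and scaled to an SD of 1 over the autosomes of a matrix. The plan, written before the data were examined, was to take the best correlate of gene density among the first 3 eigenvectors of each matrix. That rule took another than the first eigenvector on 6, 7 and 10 autosomes at PD2, PD8 and PD14, and a different one between matrices on 6 autosomes. After this was seen, the first eigenvector was used throughout, with its sign from the leading eigenvector of inter-chromosomal contacts in 400 kb blocks. Results under the planned rule are given with the other alternatives.

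A switch was a change of sign with a score difference above 0.18, the largest over the matrices of the 95th percentile of the absolute difference between random parts. Strength was the mean contact over expectation among the top 20% of bins (AA), among the bottom 20% (BB) and between them (AB), per autosome, combined as log2 of AA times BB over squared AB. Insulation used a square of 10 by 10 bins of 40 kb, filled to at least 70%. Boundaries were minima with a prominence of at least 0.2 on the log2 scale, shared when within 1 bin. Local contacts of a gene were those of its start bin with bins 80 to 400 kb away on both sides, over the expectation. Contacts of chromosome ends used the first and last 10 Mb, and coverage used 1 Mb windows.

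Genes were placed with a table of RefSeq genes on the mm10 assembly, which holds 20665 autosomal protein-coding genes. The 14 gene lists were fixed before the data were examined: SASP factors, senescence and p53 effectors, proliferation genes, lamina and chromatin architecture, enhancer-binding factors, fibroblast and matrix genes, interferon response, Hox genes, macrophage, endothelial, epithelial, neural and muscle markers, and anchor loci. Of these, 1 of the 18 interferon genes had no match in the table, and genes on chromosome X had no score. Bins with several members counted once. The percentile of a list's median was taken among 10000 random lists of as many bins with a protein-coding gene start, from the same deciles of mean score, and describes these matrices only. Random bins were drawn singly, which makes no allowance for list bins that lie side by side. Named genes followed a rule set at the same time. It names the anchor loci, up to 15 switched list members per comparison with the largest differences, and up to 3 protein-coding genes in each of the top 5 switched regions of at least 400 kb per direction, ranked by mean score difference times length. The values of 1 anchor locus are not reported here. Genes outside it are said to have been chosen after their values were seen.

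The steps were tested on simulated data. Whole-contact recovery kept 100% of 1600 bins and gave the true number for 94.7% of 548388 bin pairs. In a simulation at the depth of PD2 and PD8, 100% of 243 changed bins were found and 15 of 12012 bins were called wrongly. True and estimated scores had a Pearson r of 0.994 across bins, which are not independent replicates. Each simulated change reversed the full score of a run of bins. It was larger than some reported switches, such as -0.21 for Stag1 and 0.23 for Spp1, and detection of such small switches was not tested. Of 85 simulated boundaries 100% were found. Among 200 simulated lists each, 5% of unshifted and 70% of shifted lists lay outside the central 95%. These lists had independent bins and were longer than most of the real lists, so shorter lists and side by side bins were not tested.

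Alternatives set in advance were recovered contacts, all chromosomes, same-bin pairs, neighbouring bins left out, bins usable in all 3 matrices, 400 kb bins, the top and bottom 10% of bins, any change of sign, a fixed difference of 1 SD, thinned contacts, insulation squares of 5 and 20 bins, a prominence of 0.4, sharing within 2 bins, local contacts to 1 Mb, an expectation over all autosomes, and ends of 5 Mb. Added after the data were seen were the planned eigenvector rule and the inter-chromosomal eigenvector. Chromosomes X and Y were left out of compartments. GC content was not used, as no genome sequence was at hand.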

Results

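Contacts between DNA segments were measured by in situ Hi-C, in which chromatin is cut (here with MboI) and ends that lie close together in the nucleus are joined and sequenced. The cells were C57BL/6 mouse embryonic fibroblasts passaged serially to population doubling 2, 8 and 14, named PD2, PD8 and PD14. The series asks how genome folding accompanies senescence and the senescence-associated secretory phenotype (SASP), the release of cytokines, growth factors and proteases by ageing cells. There were 6 libraries, 2 per group, and the deposited values pool both libraries of a group, so that each group is 1 matrix of balanced contact signal in 40 kb bins of mm10. With 1 matrix per group there is no replicate error and no test between groups, and every difference is set against counting noise alone. The matrices of PD2, PD8 and PD14 held 34656477, 49647971 and 49693122 bin pairs with signal, from which 87844228, 107279081 and 104477458 whole contacts between different bins were recovered.

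Each 200 kb bin of the 19 autosomes has a compartment score, in units of the SD over bins of its matrix. Compartment A (score above 0) is the gene-rich, active side of the nucleus and compartment B (score below 0) the gene-poor, repressed side. A score difference counts as beyond noise when it is above 0.18, the 95th percentile of the absolute difference between random splits of the contacts of 1 matrix, and a switch is a change of side beyond that bound. For a list of genes, the median change is placed as a percentile among 10000 random lists matched for score. There were 14 lists and 3 comparisons, and 6 of the 42 percentiles lay outside the central 95%.

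The comparison of PD8 with PD2 asked which loci differed over the early doublings. Of 52 SASP genes, which lie in 43 bins, 18 stood further toward compartment A at PD8 than at PD2. Another 2 stood further toward B, and the others did not differ beyond noise. Differences beyond noise were common over all autosomes, at 3764 of 11940 bins in either direction. This count used 1 random part of the PD8 contacts, balanced again, against the deposited PD2 values. Mmp2, which encodes a collagen-degrading protease, and Spp1, which encodes the secreted matrix protein osteopontin, lay in B at PD2 and in A at PD8. Cdkn2a and Cdkn2b, whose products halt the cell cycle in senescence, went the same way from a PD2 score close to 0. Olig2, Kdr, Cdh5 and Stag1 went from A to B.

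The 52 scored SASP genes lay in 43 bins, of which 14 were higher beyond noise at PD8 and 1 lower, while 32 genes were within noise. The median difference was 0.092 score SD, at percentile 99.88 of the matched random lists, but in 400 kb bins it was 0.025. Mmp2 (chr8:92827290-92853421) had scores of -0.18 at PD2 and 0.25 at PD8, and Spp1 had -0.079 and 0.15. The stromelysin gene Mmp3 (chr9:7445822-7455975) stayed in B with scores of -1.07 and -0.58. Igfbp3, which encodes a carrier of insulin-like growth factors, scored -0.52 and -0.18. Among the chemokine genes in A, Cxcl1 differed by 0.21 and Cxcl5 by 0.22, while Ccl2, in B, differed by 0.11. Hgf, which encodes hepatocyte growth factor, and Tnfrsf11b, which encodes osteoprotegerin, were singled out after their values were seen, with differences of 0.75 and 0.52. The interleukin gene Il1a differed by -0.29 and remained in B, and Il6 differed by -0.037 within A.

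Cdkn2a (chr4:89274473-89294619) and Cdkn2b share a bin that scored -0.022 at PD2 and 0.24 at PD8. Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, stayed in A with a difference of 0.024. The senescence and p53 list as a whole had 4 up, 1 down and 13 within noise, with a median of 0.10 at percentile 97.3. Mki67, the gene of a protein found in cycling cells, scored 1.19 at PD2 and 0.80 at PD8. The other proliferation genes gave no common direction (2 up, 2 down and 28 within noise over all 32, percentile 29.7). The lamin gene Lmnb1 differed by -0.14 and Hmga2, which encodes a chromatin protein, by -0.0013. The cohesin subunit gene Stag1 scored 0.12 and -0.085, and the lamina and chromatin architecture list had 0 up, 5 down and 15 within noise at percentile 22.1. Enhancer-binding factors, Fosl1 (-0.0088) and Cebpb (0.079) among them, had 2 up, 0 down and 20 within noise at percentile 8.08.

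Fibroblast and matrix genes had 7 up, 0 down and 14 within noise, at percentile 96.4. Among them the fibronectin gene Fn1 was in B at PD2 (-0.19) and in A at PD8 (0.038), and the collagen gene Col1a1 differed by -0.064. The 25 Hox genes, which set position along the body axis, lie in 7 bins of 4 clusters, so that genes of a bin share 1 score. They had 0 up, 10 down and 15 within noise (4 bins down) at percentile 0.335, with a median of -0.19, although the median was 0.025 when the eigenvector was chosen by gene density. Markers of other cell types mostly lay within noise. Olig2, a regulator of glial fate, scored 0.29 at PD2 and -0.60 at PD8, the endothelial genes Kdr 0.094 and -0.18 and Cdh5 0.11 and -0.17, and the macrophage receptor gene Mrc1 -0.20 and 0.15. Macrophage markers had a median of -0.082 at percentile 2.33, but 0.080 in the inter-chromosomal eigenvector. Percentiles were 59.9 for endothelial, 2.51 for epithelial, 36.7 for neural and 9.14 for muscle markers, 53.98 for interferon response genes and 61.2 for the 16 anchor loci.

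Over the genome, 430 bins went from B to A and 216 from A to B, which is 5.38% of 12012 bins. In the same order there were 9 and 11 with a fixed difference of 1 SD, 781 and 746 with the eigenvector chosen by gene density, and 154 and 61 in the inter-chromosomal eigenvector in 400 kb bins. Random splits of the contacts of 1 matrix, from which the bound was set, gave at most 67. Regions are ranked by mean score difference times length, as fixed before the data were seen. The first by this rank from A to B held Eogt, Tmf1 and Uba3 (chr6:97000001-97800000), with mean scores of 0.30 at PD2 and -0.50 at PD8. It was followed by the regions of Epb41l4a (chr18:33600001-34200000), of Rtf2, Gcnt7 and Fam209 (chr2:172400001-173200000), of Tbcel, Grik4 and Arhgef12 (chr9:42400001-43000000), and a region with no protein-coding gene (chr8:34200001-34800000). From B to A, the top 5 included that of Tbx18 (chr9:87400001-88200000), a gene of embryonic mesenchyme, at -0.26 and 0.57, and that of Zfat (chr15:67400001-68200000) at -0.21 and 0.50. The other three held at most 1 protein-coding gene each (chr4:70800001-72000000, chr8:42200001-43000000 and chr4:30000001-31000000). At PD14, 382 of the 430 bins (88.8%) were still in A and 201 of the 216 (93.1%) still in B.

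**Figure D1:**
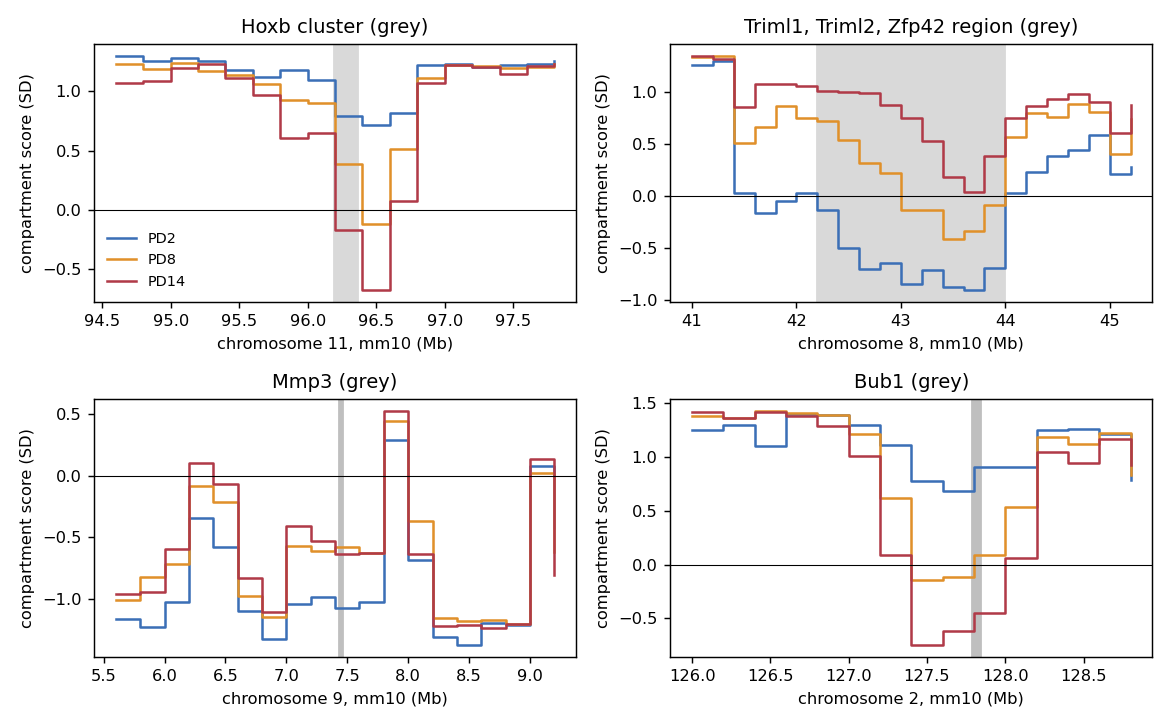
Compartment score (y axis, SD) of 200 kb bins along mm10 (x axis, Mb) in PD2 (blue), PD8 (orange) and PD14 (red) around the Hoxb cluster, the Triml1, Triml2 and Zfp42 region, Mmp3 and Bub1, each shaded grey. Bub1 scored 0.90, 0.091 and -0.45 and Mmp3 -1.07, -0.58 and -0.63 in PD2, PD8 and PD14.

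Contacts between different autosomes made up 15.4% of the signal at PD2 and 20.1% at PD8, and the share was higher on 19 of 19 autosomes. Here and below, autosomes of 1 matrix are not replicates, and each inter-chromosomal contact counts on both of its autosomes. The 95% Wilson intervals on recovered contacts were 15.60% to 15.61% at PD2 and 20.39% to 20.41% at PD8, and cover counting error only. Within autosomes, contacts at 40 to 400 kb made up 45.9% at PD2 and 37.6% at PD8, and those over 10 Mb 21.8% and 28.4%. The contact curve was flatter at PD8, with slopes of -1.42 and -1.31 between 400 kb and 4 Mb on log10 scales. Contacts among A bins were 1.52 times the distance expectation at PD2 and 1.66 times at PD8 (higher on 18 autosomes), and those among B bins 2.06 and 2.00 times (lower on 15 autosomes). Log2 compartment strength was 5.21 and 5.32, a difference of 0.10 that was -0.019 with the top and bottom 10% of bins and -0.20 with the eigenvector chosen by gene density. Topological boundaries, where contacts across a bin are depleted, numbered 3964 at PD2 and 3603 at PD8, and 83.2% of those at PD2 lay within 1 bin of one at PD8, and 91.4% of those at PD8 within 1 bin of one at PD2. Random parts of the contacts of 1 matrix shared 91.8% at PD2, 91.3% at PD8 and 91.3% at PD14.

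Local contacts of the promoter bin at 80 to 400 kb, over the expectation at their distance, were compared at the 16 anchor loci. The 95% counting interval of the PD8 to PD2 ratio excluded 1 at 1 of them, about as many as counting error alone would give. That locus was Mmp3, with a ratio of 1.17 (1.07 to 1.29), at percentile 95.4 of all bins with a gene start. Ratios were 0.955 for Il6, 0.959 for Il1a, 0.934 for Cxcl1, 1.02 for Cxcl5, 0.946 for Ccl2 and 1.02 for Igfbp3. Cdkn2a was at 0.998, Cdkn1a at 1.07, Fosl1 at 1.11, Col1a1 at 1.097 and Hmga2 at 1.06.

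**Figure D2:**
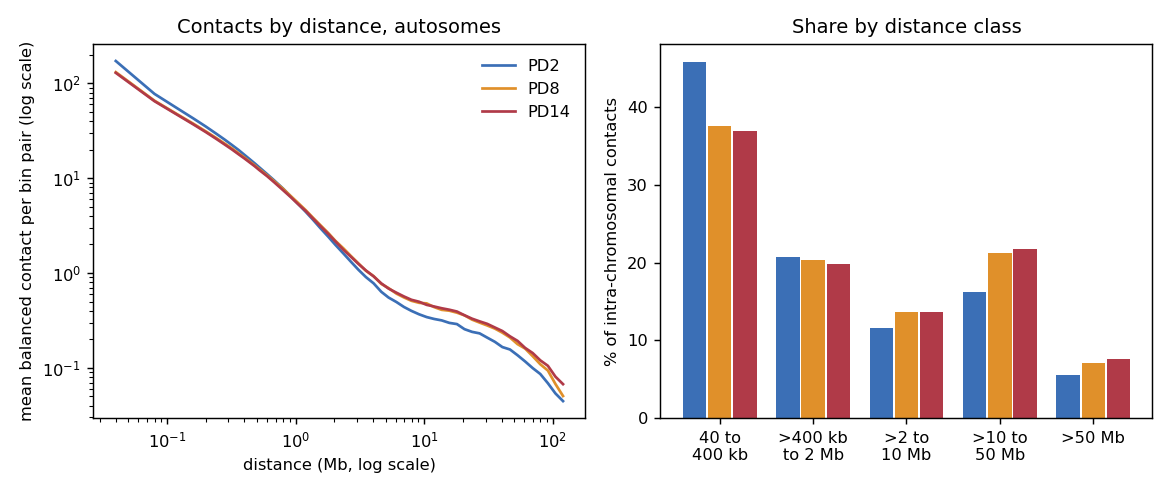
Left, mean balanced contact per pair of 40 kb bins (y axis, log scale) against distance (x axis, Mb, log scale) on autosomes of PD2, PD8 and PD14. Right, percentage of intra-chromosomal contacts (y axis) in 5 distance classes, where 40 to 400 kb holds 45.9%, 37.6% and 37.0% in the order PD2, PD8 and PD14.

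Between PD8 and PD14, the later doublings, fewer bins switched than earlier and most switches went from A to B in the first eigenvector, but with the eigenvector chosen by gene density more bins switched and most went from B to A. Hoxb1, Hoxb4, Hoxb7 and Hoxb9, the mitotic checkpoint gene Bub1, the lysozyme gene Lyz2 and the growth factor genes Ereg and Areg lay in A at PD8 and in B at PD14. The mesenchymal regulator Tcf21 and the neighbouring genes Fap and Ifih1 went from B to A. The telomerase gene Tert lay in a region that was in B at PD8 and in A at PD14.

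Hox genes had 0 up, 13 down and 12 within noise (4 of 7 bins down), with a median of -0.25 at percentile 0.62, against -0.018 with the eigenvector chosen by gene density and -0.018 in the inter-chromosomal eigenvector. Hoxb1, Hoxb4, Hoxb7 and Hoxb9, in 1 bin of chromosome 11 (Hoxb4 at chr11:96318267-96321638), scored 0.38 at PD8 and -0.17 at PD14. By cluster, the mean score was 0.64 and 0.24 for Hoxb, 0.43 and 0.29 for Hoxc, 0.74 and 0.45 for Hoxd, and 1.34 and 1.31 for Hoxa, a division by cluster made after the values were seen. In the inter-chromosomal eigenvector these means were 1.43 and 1.09 for Hoxb, 1.30 and 1.32 for Hoxc, 0.59 and 0.59 for Hoxd, and 2.21 and 2.17 for Hoxa. Bub1 (chr2:127800197-127831859) scored 0.091 and -0.45, and Mki67 0.80 and 0.93. Proliferation genes as a list had 1 up, 6 down and 25 within noise, at percentile 20.8.

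SASP genes had 3 up, 6 down and 43 within noise, with a median of -0.019 at percentile 76.3, against 0.044 in the inter-chromosomal eigenvector. Ereg and Areg, which encode ligands of the epidermal growth factor receptor and share a bin, scored 0.32 at PD8 and -0.19 at PD14. Il6 differed by -0.13, within noise, and stayed in A. Ptgs2, which encodes cyclooxygenase 2 and was singled out after its values were seen, scored 0.86 and 0.30. Mmp3 (-0.052), Igfbp3 (0.18), Cxcl1 (-0.012), Cxcl5 (0.020), Ccl2 (-0.031), Il1a (0.10), Cdkn2a (-0.058) and Cdkn1a (-0.012) were within noise, as were Lmnb1 (-0.091), Hmga2 (0.073), Fosl1 (0.030), Cebpb (-0.013) and Col1a1 (-0.10).

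Tcf21 (chr10:22817263-22820143) scored -0.015 at PD8 and 0.34 at PD14. Fap, a protease of activated fibroblasts, and Ifih1, a sensor of viral RNA, share a bin that scored -0.10 and 0.21. Lyz2 scored 0.44 and -0.28, the leukocyte gene Ptprc 0.072 and -0.14, and the interferon-induced gene Isg15 0.16 and -0.042. The epithelial genes Epcam (0.33 and -0.21) and Grhl2 (0.033 and -0.40) also went to B. Members up, down and within noise were 0, 4 and 8 for macrophage markers, 0, 2 and 10 for epithelial, 1, 1 and 15 for interferon, 3, 2 and 16 for fibroblast, and 2, 5 and 13 for lamina and architecture genes. Percentiles of these lists and of the endothelial (75.9), neural (83.5), muscle (22.8), senescence (66.9), enhancer-binding (82.5) and anchor (74.7) lists lay inside the central 95%.

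Genome-wide, 213 bins went from A to B and 141 from B to A, or 2.95% of bins. The inter-chromosomal eigenvector in 400 kb bins, with a stricter bound on the score difference, had 4 and 23. With the eigenvector chosen by gene density in each matrix, 340 went from A to B and 1414 from B to A. By the same rank, the first region toward B held Prdx6, Tnfsf4 and Tnfsf18 (chr1:161200001-161800000), at 0.16 and -0.47. Next were a region without protein-coding genes (chr4:54200001-54800000), that of Yeats4, Lyz2 and Lyz1 (chr10:117200001-117600000), another without them (chr14:58600001-59000000), and that of Etnppl, Ostc and Rpl34 (chr3:130400001-130800000). Toward A, Triml1, Triml2 and Zfp42 (chr8:43000001-44000000), genes of germ and stem cells, were at -0.23 and 0.38. The region of Adgra3 (chr5:49200001-50000000) was at -0.29 and 0.38, that of the cytokine receptor genes Ifngr1, Il22ra2 and Il20ra (chr10:19400001-20000000) at -0.30 and 0.22, and that of Clptm1l, Tert and Slc6a18 (chr13:73600001-74200000) at -0.16 and 0.35. The fifth (chr14:102200001-102600000) had no protein-coding gene.

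The inter-chromosomal share was 20.1% at PD8 and 20.7% at PD14, a difference of 0.580 percentage points in the same direction on 19 autosomes, and of 1.08 points with all chromosomes. Contacts over 10 Mb made up 28.4% and 29.4% of those within autosomes, and contacts at 40 to 400 kb 37.6% and 37.0%. A bins contacted each other less (1.66 and 1.57 times expectation, lower on 19 of 19 autosomes) and B bins more (2.00 and 2.10, higher on 19 of 19), although the B difference was -0.077 with the eigenvector chosen by gene density. Boundaries numbered 3603 and 3607, and 89.5% of those at PD8 and 89.3% of those at PD14 were shared, against 91.3% between random parts of PD8. Distal chromosome ends contacted each other 1.77 times the inter-autosomal mean at PD8 and 1.62 times at PD14, and centromere-proximal ends 1.81 and 1.74 times. Local contacts over expectation had counting intervals below 1 at 4 anchor loci, Il6 (0.871, 0.798 to 0.9495), Il1a (0.862, 0.773 to 0.961), Fosl1 (0.878, 0.788 to 0.978) and Cebpb (0.916, 0.845 to 0.993), and above 1 at Hmga2 (1.14, 1.03 to 1.27). Percentiles among bins with a gene start were 4.84, 4.21, 5.35, 10.7 and 93.4 in that order.

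**Figure D3:**
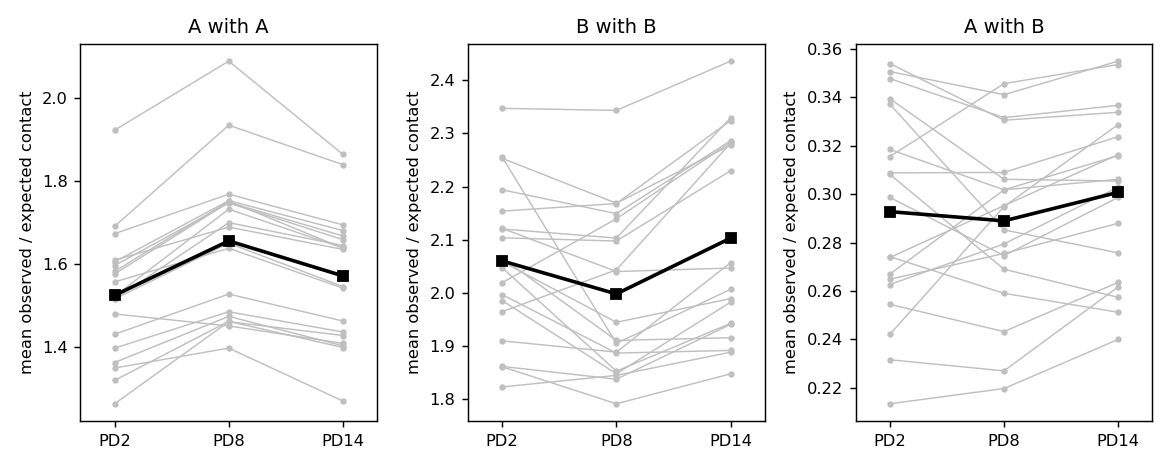
Mean observed over expected contact (y axis) among A bins, among B bins and between A and B bins in PD2, PD8 and PD14 (x axis), with 1 grey line per autosome and the mean of 19 autosomes in black. The mean for A bins was 1.52, 1.66 and 1.57 and that for B bins 2.06, 2.00 and 2.10.

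Over the whole course, PD14 against PD2, the largest score differences among listed genes belonged to Bub1, Lyz2 and Tcf21. Hoxb1, Hoxb4, Hoxb7, Hoxb9, Olig2, Kdr, Epcam and Grhl2 went from A to B, and Mmp2, Map2, Fap and Ifih1 from B to A. Relative to the expectation at their distance, local contacts of Il6, Il1a and Cebpb were lower at PD14 and those of Hmga2 and Mmp3 higher, within the central 95% of gene bins. A region of chromosome 8 with Triml1, Triml2 and Zfp42 ranked first among switches into A by score difference times length.

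Bub1 scored 0.90 at PD2 and -0.45 at PD14, Lyz2 0.88 and -0.28, and Tcf21 -0.73 and 0.34. The bin of Hoxb1, Hoxb4, Hoxb7 and Hoxb9 scored 0.79 and -0.17. Over the Hox list 17 genes in 5 bins were lower, 0 higher and 8 within noise, with a median of -0.44 at percentile 0.255, which was 0.067 with the eigenvector chosen by gene density. Olig2 differed by -0.91, Grhl2 by -0.79, Kdr by -0.60 and Epcam by -0.59. In the other direction, Map2, a neuronal microtubule gene, differed by 0.76, Mmp2 by 0.62, and Fap and Ifih1 by 0.55. Neural markers were the only other list outside the central 95%, with a median of 0.17 at percentile 98.3, 5 up, 2 down and 4 within noise. That median was 0.032 in 400 kb bins and 0.042 in the inter-chromosomal eigenvector.

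SASP genes had 15 up, 8 down and 29 within noise, with a median of 0.021 at percentile 93.3. The median was 0.13 with the eigenvector chosen by gene density and 0.16 in the inter-chromosomal eigenvector. No percentile was computed for these alternatives. Medians of other lists in the inter-chromosomal eigenvector went from -0.32 (Hox genes) to 0.29 (fibroblast genes), so 0.16 was not particular to SASP genes. Among SASP genes Igfbp3 (0.52), Mmp3 (0.44), Cxcl5 (0.24) and Cxcl1 (0.20) were higher at PD14, and Il1a (-0.19) lower. Il6 (-0.17) and Ccl2 (0.081) were within noise. Cdkn2a was higher by 0.20 and Cdkn1a by 0.012, the second within noise, and the senescence list had 6 up, 1 down and 11 within noise at percentile 96.7. Mki67 differed by -0.26 and Lmnb1, whose product is lost in senescent cells, by -0.23, and both stayed in A. Proliferation genes had 4 up, 8 down and 20 within noise at percentile 4.96, and lamina and architecture genes 1 up, 6 down and 13 within noise at percentile 20.2. Enhancer-binding factors had 1 up, 1 down and 20 within noise, with Fosl1 at 0.021 and Cebpb at 0.065, and fibroblast genes 7 up, 1 down and 13 within noise, with Col1a1 at -0.16. Hmga2 differed by 0.072. Percentiles were 39.8 for interferon response genes, 93.5 for anchor loci, and 4.3, 47.3, 3.15 and 15.3 for macrophage, endothelial, epithelial and muscle markers.

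**Figure D4:**
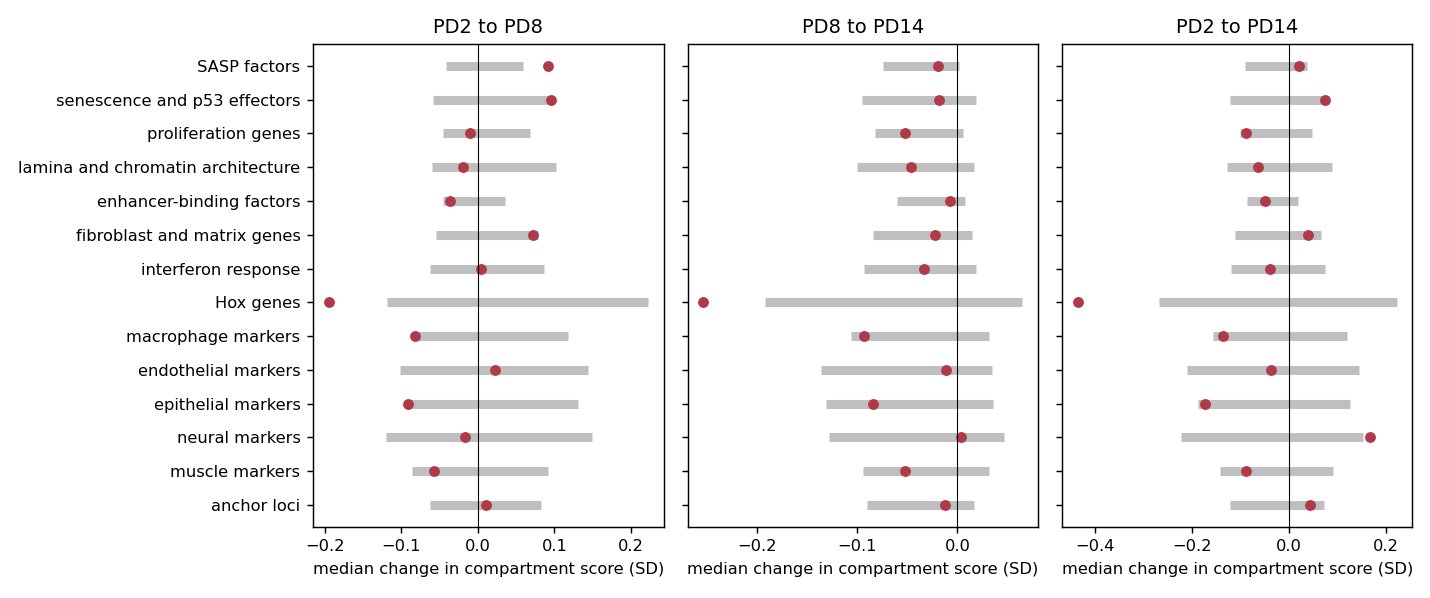
Median difference in compartment score (x axis, SD) of 14 gene lists (y axis) in each comparison, as red points, with the central 95% of 10000 matched random lists as grey bars. SASP factors from PD2 to PD8 lie at 0.092, and Hox genes at -0.19, -0.25 and -0.44, the first and last of which were 0.025 and 0.067 with the eigenvector chosen by gene density.

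Local contacts over expectation at Il6 (chr5:30013114-30019975) were 0.831 of the PD2 value (0.764 to 0.904), at Il1a 0.826 (0.741 to 0.921) and at Cebpb 0.888 (0.8199 to 0.961). Ratios above 1 were 1.21 (1.09 to 1.34) at Hmga2, 1.14 (1.02 to 1.27) at Cdkn1a and 1.13 (1.03 to 1.24) at Mmp3. Percentiles among bins with a gene start were 5.37 for Il6, 4.93 for Il1a, 14.3 for Cebpb, 96.1 for Hmga2, 92.9 for Cdkn1a and 92.3 for Mmp3. With contacts to 1 Mb the interval of Cdkn1a included 1 (1.06, 0.961 to 1.18). At the other 10 anchor loci the interval included 1, as for Cdkn2a (1.07) and Mki67 (0.935). The 1 Mb window of Cdkn2a, a locus that passaged fibroblasts can lose, had a coverage ratio of -0.022 on the log2 scale, at percentile 34.1 of 2382 windows. Coverage per autosome at PD8 or PD14 was 0.978 to 1.02 of that at PD2, so no gain or loss of a whole autosome in most cells was visible. Some extreme windows overlapped switched regions. They were chr8:42000001-43000000, in the Triml1 region (log2 0.19 from PD8 to PD14), and chr2:172000001-173000000, in the Rtf2 region (-0.19 from PD2 to PD14). Others did not, as chr11:3000001-4000000 (0.42 from PD2 to PD14). An effect of coverage on scores was not tested.

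From PD2 to PD14, 553 bins went from B to A and 406 from A to B, or 7.98% of bins. In the same order there were 96 and 89 with a fixed difference of 1 SD, and 1836 and 751 with the eigenvector chosen by gene density. The inter-chromosomal eigenvector in 400 kb bins, with a stricter bound on the score difference, had 352 and 107. The switched region of Triml1, Triml2 and Zfp42 (chr8:42200001-44000000) scored -0.67 at PD2 and 0.64 at PD14. Dipk2a and Slc9a9 (chr9:93800001-95400000), Kif16b (chr2:141800001-143000000), Immp2l and Lrrn3 (chr12:41000001-42400000) and Adgra3 (chr5:49200001-50000000) followed, the last with -1.11 and 0.38. Toward B the regions ranked first held Tmem38b (chr4:53800001-54800000), the transcription factor gene Sox11 (chr12:26600001-27400000, 0.65 and -0.50), and again Eogt, Tmf1 and Uba3 (chr6:97000001-97800000). The others held Gpat2, Fahd2a and Kcnip3 (chr2:127400001-128000000), in the same stretch as Bub1, and Armh1, Tmem53 and Rnf220 (chr4:117200001-117800000). The inter-chromosomal share differed by 5.23 percentage points, contacts at 40 to 400 kb by -8.87 and those over 10 Mb by 7.69, with the same direction on 19 of 19 autosomes for each. Log2 compartment strength was 5.21 and 5.20, but differed by -0.14 in 400 kb bins, -0.18 with the top and bottom 10% of bins and -0.93 with the eigenvector chosen by gene density. Of the boundaries, 81.4% of those at PD2 and 89.2% of those at PD14 were shared, against 91.8% and 91.3% between random parts of each matrix.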

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

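The tests of mitochondrial contacts, of the far share and of run marks were chosen after the results were seen; the dilution test was set before. Contacts between the mitochondrial genome and autosomes, which no comparison above uses, were present in all 3 matrices. They made up 688 ppm of autosomal contacts at PD2, 207 at PD8 and 136 at PD14. Mitochondrial and nuclear DNA lie in different organelles, so such contacts were used to test for random ligation.

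The higher inter-chromosomal share at PD8 and PD14 was weighed against technical explanations. Random ligation that dilutes real contacts would cut the compartment contrast of inter-chromosomal contacts at PD8 to at most 0.768 of that at PD2, but the ratio was 0.940, and at PD14 it was 0.828 against 0.747. More ligation between unrelated molecules would raise mitochondrial contacts with autosomes, but per same-bin mitochondrial contact they were 9.10 at PD2, 8.10 at PD8 and 4.75 at PD14. Both tests argue against random ligation as the whole cause, while a part remains possible. At PD14 the contrast ratio lay nearer to the diluted value than to an unchanged contrast, so by that test the part could be large. The dilution test takes the contrast of real contacts to be alike in the matrices. The mitochondrial test takes contacts between mitochondrial genome and autosomes to come from random ligation alone. It also takes same-bin mitochondrial contacts (6307, 2601 and 2823 at PD2, PD8 and PD14) to follow the amount of mitochondrial DNA. Neither was tested. Of the PD2 libraries, 1 carries a run mark that no PD8 or PD14 library has, so a run difference and PD2 cannot be told apart in pooled matrices, and an effect of population doubling stays open and untested.

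The lower share of contacts at 40 to 400 kb at PD8 and PD14 could come from undigested or short fragments at PD2. These would add contacts only within bins or between neighbouring bins. Among contacts over 400 kb the share over 10 Mb would then be alike, but it was higher at PD14 than at PD2 by 6.54 percentage points. This argues against short fragments as the whole cause. However, same-bin contacts, which these shares leave out, made up 18.95% of recovered contacts at PD2, 11.16% at PD8 and 10.2% at PD14. More short fragments at PD2 could give that difference, so a part remains possible. A run difference stays open here as well.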

How the results depend on the processing

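The eigenvector rule set in advance and the inter-chromosomal eigenvector were compared only after the results were seen, and the other alternatives were planned. No paired analysis was possible because each matrix pools the libraries of its group, and for the same reason leaving out a replicate was not possible. Values are listed for PD2 to PD8, PD8 to PD14 and PD2 to PD14, in that order. Of 378 alternative values, 96 were local contacts at anchor loci, of which 95 stayed within counting error and 1 moved. Of the others, 97 stayed within counting spread or, for counts, within a set factor. Another 176 moved further than that, and 9 had the opposite sign to a called difference. Numbers of switches have no sign, so a change in their main direction is not among the 9. Sign changes of differences that were not called are not among them either. The cause was not tested for any of the changes unless stated.

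All alternatives kept the direction of the inter-chromosomal share and of the shares at 40 to 400 kb and over 10 Mb. The inter-chromosomal differences were 4.796, 0.674 and 5.47 percentage points on recovered contacts, 4.64, 1.08 and 5.72 with all chromosomes and 5.31, 0.709 and 6.01 with same-bin pairs. For 40 to 400 kb they were -8.79, -0.543 and -9.33 on recovered contacts and -6.39, -0.5395 and -6.93 without neighbouring bins, and for over 10 Mb 6.84, 0.8902 and 7.73 and 6.29, 1.16 and 7.45. The share over 2 to 10 Mb at PD14 minus PD8 was 0.013 points, but -0.017 on recovered contacts and -0.020 without neighbouring bins. With bins usable in all 3 matrices, 6 of 6 values stayed within counting error.

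Compartment strength depended on the processing. Log2 strength differed by 0.029, -0.17 and -0.14 in 400 kb bins, -0.019, -0.16 and -0.18 with the top and bottom 10% of bins and -0.20, -0.73 and -0.93 with the planned eigenvector rule, so that the first value changed sign with 10% of bins and with the planned rule. AA differed by 0.14, -0.081 and 0.062 in 400 kb bins, 0.13, -0.11 and 0.016 with 10% of bins, 0.14, -0.092 and 0.046 in thinned contacts and 0.10, -0.12 and -0.014 with the planned rule. BB differed by -0.067, 0.083 and 0.016, -0.16, 0.054 and -0.11 and -0.11, -0.077 and -0.18 in 400 kb bins, with 10% of bins and with the planned rule. The lower A and higher B contacts of PD14 against PD8 kept their direction except for BB under the planned rule.

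Switches numbered 326, 182 and 473 in 400 kb bins, of which there are fewer, 20, 1 and 185 with a fixed difference of 1 SD, 1527, 1754 and 2587 with the planned rule and 215, 27 and 459 in the inter-chromosomal eigenvector. The planned rule took different eigenvectors in different matrices, which its construction turns into switches. The inter-chromosomal eigenvector had 400 kb bins and a stricter bound on the score difference, so its lower numbers are partly built in. The share going from B to A was 66.6%, 39.8% and 57.7% as reported, 45%, 100% and 51.9% with 1 SD, 51.1%, 80.6% and 70.97% with the planned rule and 71.6%, 85.2% and 76.7% in the inter-chromosomal eigenvector. Any change of sign and thinned contacts left the counts within 1.5 times those reported. The excess of A to B switches from PD8 to PD14 was therefore found neither with the planned rule nor in the inter-chromosomal eigenvector.

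Shared boundaries were 84.6%, 87.3% and 82.5% with squares of 5 bins, 79.7%, 90.9% and 78.5% with 20 bins, 85.7%, 91.6% and 83.3% in thinned contacts and 85.6%, 91.7% and 83.9% within 2 bins. PD2 had more boundaries than PD8 and PD14 under each alternative, with 3800, 3472 and 3458 at PD2, PD8 and PD14 in thinned contacts. Centromere-proximal contacts differed by -0.048, -0.10 and -0.15 on the log2 scale with 5 Mb ends and by 0.039, -0.054 and -0.015 on recovered contacts. Of 96 values of local contacts at anchor loci, 95 stayed within counting error and 1, at Lmnb1, moved. With contacts to 1 Mb the PD14 to PD2 ratio of Cdkn1a was 1.06 (0.961 to 1.18) against 1.14 (1.02 to 1.27), and the call ended because the ratio lay closer to 1. Intervals above 1 arose for Cdkn2a from PD8 to PD14 (1.13, 1.03 to 1.23) and from PD2 to PD14 (1.097, 1.002 to 1.201) and for Igfbp3 from PD2 to PD14 (1.11, 1.03 to 1.197).

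In 400 kb bins, 17 of 42 median score differences of the lists stayed within counting spread. SASP factors had 0.025, -0.032 and 0.0091 and senescence effectors 0.059, -0.011 and 0.032. Proliferation genes had -0.011, -0.036 and -0.037 and architecture genes -0.033, -0.063 and -0.065. Enhancer-binding factors had -0.0043, 0.0060 and 0.00061 and fibroblast genes 0.062, 0.0045 and 0.037. Interferon genes had 0.017, -0.038 and -0.069 and Hox genes -0.38, -0.22 and -0.64. Macrophage markers had -0.037, -0.11 and -0.14 and endothelial markers -0.032, -0.0082 and -0.034. Epithelial markers had -0.070, -0.028 and -0.091 and neural markers 0.077, 0.025 and 0.032. Muscle markers had -0.029, -0.0085 and -0.044 and anchor loci 0.022, -0.027 and 0.013.

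In contacts thinned to the depth of PD2, 29 of 42 medians stayed within counting spread. SASP factors had 0.081, -0.018 and 0.042 and senescence effectors 0.10, -0.018 and 0.076. Proliferation genes had -0.0030, -0.058 and -0.078 and architecture genes -0.045, -0.063 and -0.086. Enhancer-binding factors had -0.010, 0.0017 and -0.035 and fibroblast genes 0.062, -0.014 and 0.025. Interferon genes had 0.015, -0.040 and -0.066 and Hox genes -0.19, -0.20 and -0.39. Macrophage markers had -0.066, -0.10 and -0.12 and endothelial markers 0.039, -0.0025 and -0.035. Epithelial markers had -0.10, -0.066 and -0.17 and neural markers 0.033, -0.00021 and 0.15. Muscle markers had -0.0069, -0.063 and -0.082 and anchor loci 0.016, -0.022 and 0.037.

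With the planned eigenvector rule, 10 of 42 did so, and the Hox difference had the opposite sign in the first and last comparison. SASP factors had 0.087, 0.012 and 0.13 and senescence effectors 0.071, 0.030 and 0.092. Proliferation genes had 0.019, 0.028 and -0.058 and architecture genes -0.12, 0.0099 and -0.023. Enhancer-binding factors had -0.039, -0.00080 and -0.046 and fibroblast genes 0.029, 0.055 and 0.061. Interferon genes had -0.0038, -0.0085 and 0.015 and Hox genes 0.025, -0.018 and 0.067. Macrophage markers had -0.15, 0.018 and -0.14 and endothelial markers 0.0075, 0.038 and 0.10. Epithelial markers had 0.015, -0.031 and 0.12 and neural markers -0.021, 0.082 and 0.32. Muscle markers had -0.10, -0.021 and -0.012 and anchor loci 0.0026, 0.022 and 0.17.

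In the inter-chromosomal eigenvector 3 of 42 did so, and macrophage markers had the opposite sign from PD2 to PD8. The SASP median was higher than reported in each comparison, as were those of fibroblast and interferon genes. SASP factors had 0.16, 0.044 and 0.16 and senescence effectors 0.050, -0.012 and 0.018. Proliferation genes had 0.0083, -0.011 and 0.016 and architecture genes 0.035, -0.0096 and 0.10. Enhancer-binding factors had 0.11, 0.018 and 0.14 and fibroblast genes 0.16, 0.10 and 0.29. Interferon genes had 0.10, 0.0062 and 0.18 and Hox genes -0.32, -0.018 and -0.32. Macrophage markers had 0.080, 0.015 and 0.083 and endothelial markers -0.0031, 0.024 and 0.065. Epithelial markers had -0.020, -0.039 and -0.084 and neural markers 0.052, 0.019 and 0.042. Muscle markers had -0.13, -0.030 and -0.17 and anchor loci 0.056, -0.040 and 0.014. Depth limits local contacts: the Cdkn1a value at PD14 rests on 585 contacts and the Il6 value at PD2 on 1168.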

Other observations

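The tests of switches and of the direction of scores were set before their results were seen, and the gene families were chosen after. Counting noise may give switches in eigenvectors, but random parts of 1 matrix differed at 67 bins at most, against 354 or more between matrices. The bound for a switch was set from these same parts, so a low count was partly built in. A chromosome-scale gradient in the eigenvector need not appear in inter-chromosomal contacts. Of the switched bins, 95.5% from PD2 to PD8, 87.0% from PD8 to PD14 and 94.2% from PD2 to PD14 differed in the same direction there. However, chromosome ends contacted each other above the inter-autosomal mean, 1.82 times for proximal and 1.84 times for distal ends at PD2. A gradient by position could therefore appear there too, and this test cannot exclude it. With 1 random part of the PD8 contacts, 3764 of 11940 bins passed the bound from PD2 to PD8. These bins are a minority, though more than counting noise alone should pass at a bound from the 95th percentile. The PD8 part was balanced again and set against the deposited PD2 values, so a processing difference may have added to their number. How many single switches counting noise gave stays open, and so does a gradient by position. Differences between libraries or runs remain open, because the libraries are pooled.

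A hypothesis was that scores move on in 1 direction over the doublings. With the PD8 contacts split at random, so that noise in PD8 could not enter both differences, the Pearson r between the differences from PD2 to PD8 and from PD8 to PD14 was 0.449 across 11940 bins, and above 0 on 19 of 19 autosomes. Bins are not independent replicates. Of 3764 bins with a difference beyond noise from PD2 to PD8, 71.7% had a later difference of the same sign, whatever its size. This is consistent with a gradual course, and also with any gradual technical difference among the 3 matrices.

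Gene families were read from symbols, with 15 families and 45 percentiles computed, of which 8 lay outside the central 95%. Vomeronasal receptor genes, in B, had medians of 0.091 from PD2 to PD8 and 0.090 from PD2 to PD14. Both were at percentile 100 of the matched lists, and that from PD8 to PD14 was at 99.7. The 354 genes lay in 141 bins, of which 27 were higher and 0 lower beyond noise from PD2 to PD8. Random bins were drawn singly, so percentiles of families make no allowance for bins that lie side by side. Serpin genes were at percentiles 99.95 from PD2 to PD8, 99.99 from PD2 to PD14 and 56.5 from PD8 to PD14. Potassium channel genes were at percentiles 0.39, 0.69 and 0.35 from PD2 to PD8, PD8 to PD14 and PD2 to PD14. The mean coverage of chromosome X was 0.730, 0.708 and 0.725 of the median autosome at PD2, PD8 and PD14.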
